A study of Mus musculus with 6 samples.

How the data were processed

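RNA sequencing libraries had been made from total RNA of mouse CD8 T cells with a NEBNext Ultra II RNA kit after extraction with RNeasy Plus Micro columns, per the labels' protocols. The labels name 3 libraries from cells activated for 48 h with DMSO and 3 from cells activated for 48 h with 10 nM ponatinib. Groups and replicate numbers were taken from the sample titles. The labels' protocols do not say whether the kit kept the strand of the RNA.

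The authors deposited 1 table with 1 column per library. Its name speaks of normalized counts, but every column of the deposited table adds up to the same total, 1000000, as TPM do (transcript abundances relative to the library total), and in genes with 1 transcript the low products of value and transcript length piled up near a value, as they do in TPM. The deposited values were therefore treated as TPM. TPM divide each gene's reads by its effective length and by the library's sum, so a change in a few abundant genes moves all others. The submitters' processing notes name fastp 0.19.5, Salmon 1.5.1 and DESeq2 1.22.1 and the genome build GRCm38, without saying which step each one served. How transcripts were summed to genes, and whether rows were filtered, is not given in the sources used here.

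The table held 43072 rows, of which 22095 carried gene identifiers and 20977 carried transcript identifiers. Gene names and coordinates came from GENCODE mouse release 21 on GRCm38, matched on identifiers without their version; 22011 gene rows and 20793 transcript rows were found there. Only 11 row identifiers carried the same version as that release, so the authors' annotation was another one. Of the transcript rows found, 20772 lay outside the basic set of the annotation, and 20784 belonged to a gene that also had a row. Transcript rows were added to their gene in each library, which gave 22288 rows; using gene rows alone was tried as an alternative. No column belonged to a sample outside the series.

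TPM keep no depth, so the number of reads per library is unknown and no counting interval is given. From pile-ups of low values in genes with 1 transcript, 1 read on a transcript of 1000 bases was worth an estimated 0.0423 to 0.0528 TPM, depending on the library. Reads were not recovered from these values. With 6 libraries the precision is set by the spread between replicates, and the median standard error of a log2 fold change was 0.08.

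The design fixed before the data were examined had assumed normalized counts. Because the values are TPM, the test was kept as written and its minimum of 10 and the threshold of 100 for named genes now apply on the TPM scale. Genes with a mean of at least 10 TPM over the 6 libraries were kept, 6816 in all. Values were transformed to log2(TPM + 1), which understates the change of low genes, and ponatinib was compared with DMSO with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. All tests were two-sided. A gene was called when its Benjamini-Hochberg adjusted p over all kept genes was under 0.05. Every adjusted p of a gene is from that limma fit. Folds without the log2 scale are ratios of mean TPM. The replicate number was left out of the fit, and a fit with it as a block was an alternative.

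Gene lists were written from textbook knowledge before the data were examined: 32 in all, of which 27 had at least 3 kept members and were tested. Each was compared with all other kept genes with limma's camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. Beside it camera was run with an estimated correlation and on ranks, and fry was run for movement of a list in 1 direction or in either. For each list the number of called members is given over all kept genes and also adjusted over the list alone. The lists cover naive and stem-like memory genes, effector genes, inhibitory receptors, genes induced by the T cell receptor, its signalling components, ERK feedback genes, kinases known as ponatinib targets, DNA replication, mitosis, cyclin-dependent kinase inhibitors, glycolysis, hypoxia, oxidative phosphorylation, sterol and fatty acid synthesis, the ATF4 response, the unfolded protein response, heat shock, ribosome biogenesis, interferon response, cytokine receptors, type 2 and type 17 cytokines, homing, p53 targets and the BCL2 family. Others cover markers of B cells, CD4 T cells, myeloid cells, NK cells, and erythroid cells and platelets, transcripts of RNA quality, and sex-linked transcripts.

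Named genes followed a rule fixed before the data were examined. They are the 10 with the largest fold change in each direction among called genes whose groups did not overlap and whose higher group had a mean of at least 100 TPM, up to 4 members of each list with the smallest p, and 20 panel genes named whatever their result, of which 1 is not reported here. In all, 476 higher and 169 lower genes qualified for the first part. Where a gene outside this rule is named, the text says that it was chosen after its values were seen.

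The steps were tested on simulated TPM for the same comparison, drawn with a coefficient of variation of 4.85% and 200 changed genes, with 6792 genes tested. A fold of 1.25 was called in 96.9% of 65 genes and a fold of 1.5 in 100% of 64, and 13 unchanged genes were called. A list of genes all lowered by a fold of 1.5 was called, and 0 of 20 lists of randomly picked unchanged genes were. Beyond counting noise, every gene was given the same variation, the median over genes of at least 100 TPM, and no library was set apart. The shares called therefore do not carry over to genes that vary more between libraries. Genes were drawn independently of each other. The simulation therefore does not show how the list tests behave when members vary together between libraries.

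Alternatives fixed before the data were examined were other scalings (the same total, medians of ratios, quantile normalization), pseudocounts of 0.1 and 10, no filter and a minimum of 100, precision weights per value (vooma) or per library (array weights), robust empirical Bayes, a minimum fold of 1.2 (treat), the replicate block, each library left out in turn, and the other list tests. Gene rows alone, a minimum of 1 TPM, and removal of mitochondrially encoded genes with rescaling were chosen after seeing the data. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

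Some genes cannot be told from near-identical copies by short reads: Gapdh, Pgk1, Pgam1 and Eno1 have processed pseudogenes, and Bcl2a1b and Bcl2a1d are almost alike, so their values are uncertain. Values of genes that overlap another gene, or one on the other strand, are uncertain too, since use of the strand is not stated.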

Results

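RNA was measured in mouse CD8 T cells, the lymphocytes that kill infected or transformed cells. Naive cells purified from spleens of C57BL/6 mice, an inbred laboratory strain, had been activated for 48 h with antibodies against CD3 and CD28, which trigger the T cell receptor and its co-receptor, in medium with IL-2. There were 3 libraries from cells that received the solvent DMSO and 3 from cells that received 10 nM ponatinib, an inhibitor of BCR-ABL and of many other kinases. Transcript levels were in TPM, and between 6551 and 6972 genes per library reached 10 TPM. The labels do not say that the replicates were separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

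The comparison asked which transcripts differed when CD8 T cells were activated with ponatinib rather than with its solvent. With ponatinib, all 14 kept genes of the hypoxia response fell, as did 17 of 19 of glycolysis, 19 of 20 of the ATF4 amino acid response, 17 of 22 of sterol synthesis and 8 of 13 of fatty acid synthesis. Scd1, which encodes stearoyl-CoA desaturase, fell from 61.1 ± 4.57 to 1.46 ± 0.331 TPM (SD, n = 3 per group), a 41.7-fold lower mean, and Slc16a3, which encodes a lactate exporter, fell from 267 ± 25.2 to 17.3 ± 3.72 TPM. The chemokine genes Ccl1, Xcl1, Ccl3 and Ccl4 rose, Xcl1 from 665 ± 152 to 3151 ± 132 TPM. S1pr1, Klf2, Il7r and Tcf7, known from naive and memory T cells, rose as well, while Ccr7, known from naive T cells, fell. The list of naive and stem-like memory genes was not called (camera adjusted p = 0.115). The costimulatory receptor gene Tnfrsf4 fell. Inhibitory receptor genes split, with Lag3 and Tigit lower and Cd160 and Vsir higher. Of 35 kept DNA replication genes 12 rose and 0 fell, and of 30 mitosis genes 14 rose and 0 fell. With 1 library left out as few as 6 and 7 were higher, and with medians of ratios as the scaling 1 of each list was lower. Among all 6816 kept genes 1859 rose and 622 fell. Relative to the median of all kept genes, the replication list lay at -0.0055 and the mitosis list at 0.099. Mki67, a marker of cycling cells, was not called.

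Of 6816 kept genes, 1859 were higher and 622 lower with ponatinib, and 42 of the higher and 88 of the lower differed by more than 1 on the log2 scale. The groups did not overlap in 3499 kept genes, 51.3%, where chance gives 10%. The median of all kept genes lay at 0.10 rather than 0, and the split depended on the scaling: medians of ratios gave 1059 higher and 1138 lower genes, so that the share of calls that were higher was 48.2% in place of 74.9%, and quantile normalization gave 55.8%. All 1059 and all 622 were shared between both scalings, and no gene was called in opposite directions under any setting. The number of higher genes was 2659 without DMSO replicate 3, 1174 without DMSO replicate 1, and 1092 and 1037 without ponatinib replicates 2 and 3; the number of lower genes was 668 without DMSO replicate 3.

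The first principal component held 72.7% of the variance and separated the treatments. The second held 16.9% and set DMSO replicate 3, at -14.1, apart from DMSO replicates 1 and 2, at 6.27 and 9.89. Spearman correlations across genes, which are not independent replicates, were 0.991 to 0.995 within ponatinib, 0.980 to 0.994 within DMSO and 0.942 to 0.967 between groups. Mitochondrially encoded genes held 4.78% of TPM in DMSO replicate 3, 9.76% and 10.7% in DMSO replicates 1 and 2, and 7.16% to 8.19% with ponatinib.

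**Figure D1:**
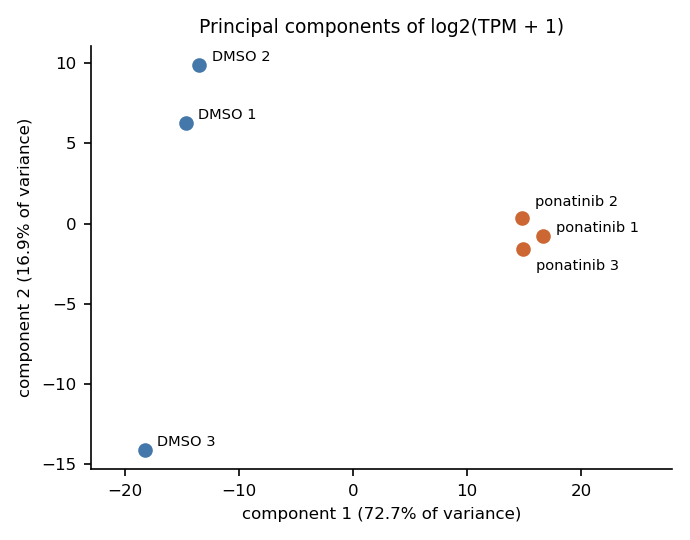
First (x axis) and second (y axis) principal component scores of log2(TPM + 1) over the 6816 kept genes, with 1 point per library, blue for DMSO and orange for ponatinib. The 3 ponatinib libraries lie together at the right, and DMSO replicate 3 lies at -14.1 on the second component, below the other DMSO libraries.

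Hypoxia response genes fell together: all 14 kept members were lower, with a median log2 fold change of -1.41. Bnip3, which encodes a mitophagy receptor, fell from 142 ± 42.7 to 14.3 ± 4.07 TPM (log2 fold change -3.21, SE 0.23, adjusted p = 1.56e-04). Ddit4, an inhibitor of mTORC1 signalling, fell from 138 ± 36.2 to 21.2 ± 2.39 TPM, and Ankrd37 and the collagen prolyl hydroxylase gene P4ha1 fell by 1.57 and 1.04 on the log2 scale. All 14 were also lower when adjusted over the list alone. The list was called lower by camera (adjusted p = 1.99e-18), and its adjusted p was 0.312 with an estimated correlation. DMSO replicate 3 had the highest Bnip3 level, 189 TPM, against 129 and 107 TPM in the other DMSO libraries.

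Glycolysis and lactate genes showed 17 of 19 kept members lower and 0 higher, with a median of -0.86 and 17 lower adjusted over the list alone. With DMSO replicate 3 left out, 1 was higher and 16 of 18 lower. Slc16a3 had the largest fold change (-3.89, SE 0.15, adjusted p = 1.05e-05). Tpi1, encoding triosephosphate isomerase, fell from 1692 ± 67.3 to 640.3 ± 58.6 TPM, and Pfkl and Gpi1, enzymes of the upper pathway, fell by 1.19 and 0.73 on the log2 scale. Pfkfb3 and Slc16a1, at -0.22 and 0.10, did not pass the test; both were looked at after their values were seen. The camera adjusted p was 9.34e-21, and it was 0.312 with an estimated correlation. Slc16a3 (ENSMUSG00000025161) lies on the plus strand of chromosome 11, at 120948480 to 120960868 of GRCm38.

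Fatty acid synthesis genes had 8 of 13 kept members lower and 1 higher, with a median of -0.48. Besides Scd1 (log2 fold change -4.66, SE 0.12, adjusted p = 1.48e-06), the desaturase gene Fads2 fell from 68.1 ± 3.76 to 6.49 ± 1.72 TPM, Scd2 from 341 ± 18 to 76.5 ± 16.9 TPM, and Srebf1, a transcription factor of lipid synthesis, from 64.2 ± 3.41 to 35.4 ± 1.72 TPM. The member that rose was Fasn, fatty acid synthase, from 123 ± 17.4 to 172 ± 10.0 TPM (adjusted p = 0.00791), named after its value was seen. The same counts held adjusted over the list alone, the camera adjusted p was 1.66e-06, and it was 0.312 with an estimated correlation. With a minimum mean of 100 TPM, which leaves out Scd1, Fads2 and Srebf1, the list's adjusted p was 0.138. Scd1 (ENSMUSG00000037071) lies on the minus strand of chromosome 19, at 44394455 to 44407879.

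Sterol synthesis genes had 17 of 22 kept members lower and 0 higher, with a median of -0.48. Fdps, farnesyl diphosphate synthase, fell from 366 ± 6.06 to 147 ± 12.7 TPM, Pmvk from 75.4 ± 2.98 to 37.8 ± 0.573 TPM, and Nsdhl and Mvd fell by 0.92 and 0.76 on the log2 scale. Adjusted over the list alone, 18 were lower. The camera adjusted p was 3.58e-16, and it was 0.312 with an estimated correlation.

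Genes of the ATF4 and amino acid response, which supply and sense amino acids, showed 19 of 20 kept members lower and 0 higher, with a median of -0.80. Asns, asparagine synthetase, fell from 114 ± 49.8 to 18.4 ± 3.94 TPM (log2 fold change -2.51, SE 0.27, adjusted p = 7.80e-04). Trib3 fell from 51.5 ± 15.1 to 5.52 ± 0.296 TPM and Gpt2 from 19.4 ± 8.25 to 1.47 ± 0.204 TPM, while the proline and serine synthesis genes Aldh18a1 and Psph fell by 0.74 and 1.15 on the log2 scale. The 19 were also lower adjusted over the list alone. The camera adjusted p was 7.05e-19, and it was 0.386 with an estimated correlation. In DMSO replicate 3, Asns stood at 171 TPM against 89.6 and 81.4 TPM in DMSO replicates 1 and 2, and without that library its log2 fold change was -2.17.

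**Figure D2:**
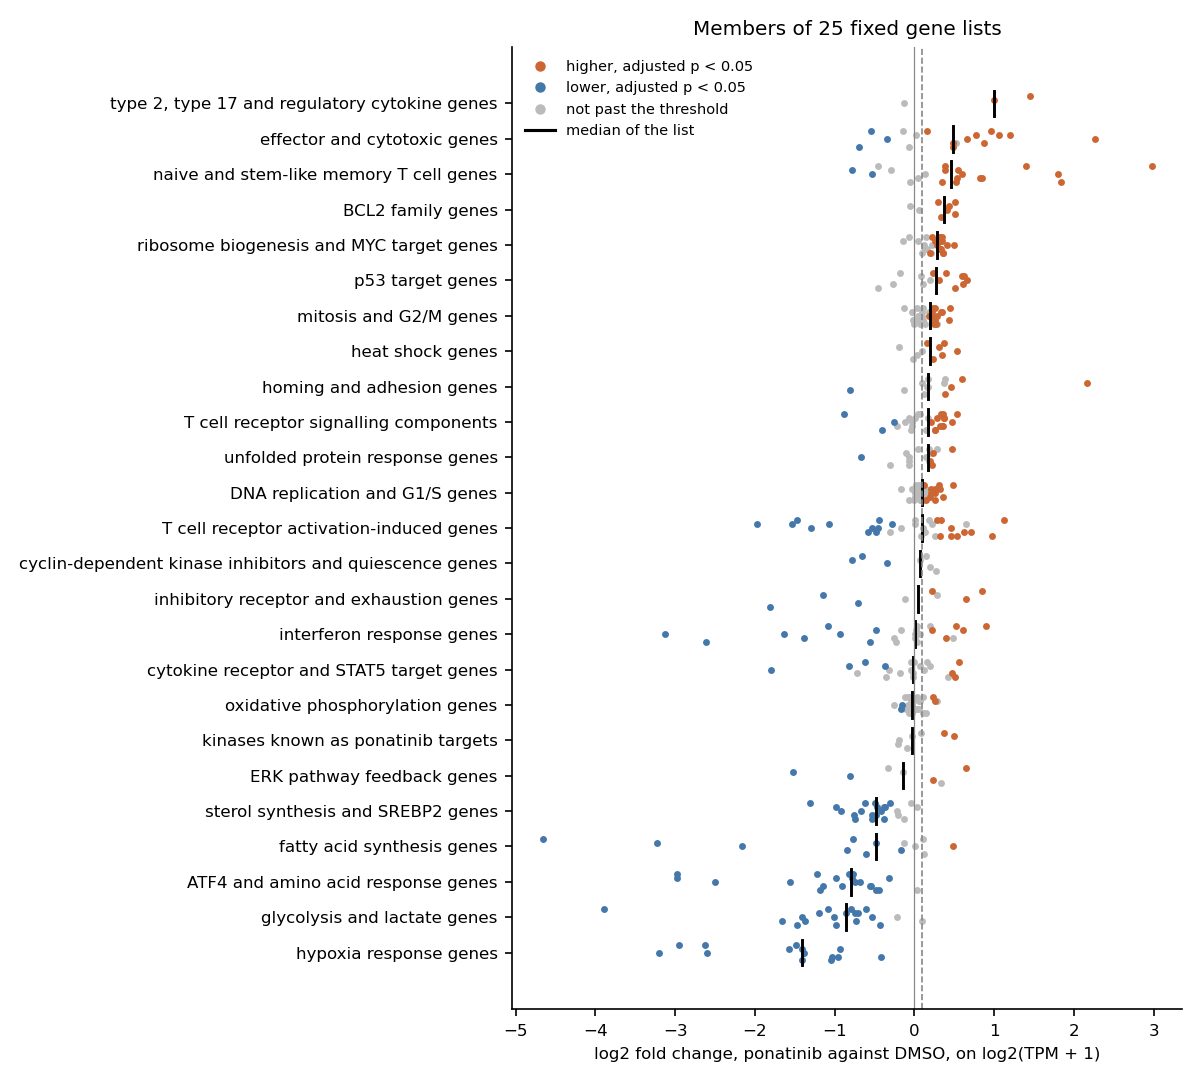
Log2 fold change of ponatinib against DMSO (x axis) for the kept members of each fixed gene list with 3 or more of them, lists of other cell types and RNA quality left out; each point is a gene, orange if called higher, blue if called lower and grey otherwise, and the black tick is the list's median. The dashed line marks the median of all kept genes, 0.10, and the medians of the hypoxia, glycolysis, ATF4, fatty acid and sterol lists lie from -1.41 to -0.48.

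Effector and cytotoxic genes moved in both directions, with 10 of 17 kept members higher and 3 lower and a median of 0.48; the counts were the same adjusted over the list alone. Xcl1, a chemokine that attracts dendritic cells, rose by 2.27 on the log2 scale (SE 0.15, adjusted p = 1.25e-04), Ccl3 rose from 649 ± 27.1 to 1362 ± 88.8 TPM and Ccl4 from 416 ± 14.1 to 812 ± 26.3 TPM. Tbx21, which encodes the transcription factor T-bet, fell from 48.3 ± 4.75 to 32.8 ± 2.58 TPM. Gzmb, encoding granzyme B, fell from 4809 ± 1637 to 2889 ± 346 TPM (log2 fold change -0.69, SE 0.20, adjusted p = 0.0317). The list was not called (camera adjusted p = 0.169; 0.634 with an estimated correlation). Its adjusted p was 0.00758 without DMSO replicate 3, 0.0451 with medians of ratios and 0.0191 with a minimum mean of 1 TPM. Without ponatinib replicates 1, 2 and 3 there were 7, 6 and 5 higher members and 1 lower each time.

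DMSO replicate 3 decided several effector values. Ifng, encoding interferon gamma, was higher with ponatinib, at 743 ± 63.2 against 370.2 ± 255 TPM (log2 fold change 1.2, SE 0.38, adjusted p = 0.0387), but DMSO replicate 3 stood at 665 TPM and the other DMSO libraries at 216 and 230 TPM. Without DMSO replicate 3 the log2 fold change of Ifng was 1.73 (adjusted p = 2.79e-06); without any 1 of the others the call was lost, at 0.118 and 0.108 without DMSO replicates 1 and 2 and 0.0874, 0.0982 and 0.119 without ponatinib replicates 1, 2 and 3. It was also lost with medians of ratios (0.0502) and quantile normalization (0.0534). Gzmb was 6696 TPM in DMSO replicate 3 against 3952 and 3777 TPM; its log2 fold change was -0.43 without that library, and its call was lost without ponatinib replicates 1, 2 and 3 (adjusted p of 0.11, 0.0788 and 0.0629) and with quantile normalization (0.0657). No filter (0.0956) and robust empirical Bayes (0.0793) ended the Gzmb call too. Prf1, encoding perforin, did not pass the test (0.52, adjusted p = 0.117) but did without DMSO replicate 3 (0.85, adjusted p = 1.92e-05).

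Ccl1, which encodes a chemokine for the receptor CCR8, had the largest fold change of all named genes. It was listed at 0.327, 1.09 and 0 TPM in the DMSO libraries and at 146, 141 and 153 TPM with ponatinib (log2 fold change 6.72, SE 0.23, adjusted p = 8.28e-06). In the annotation used it is a long locus on the minus strand of chromosome 11, at 82176657 to 82305690 of GRCm38 (ENSMUSG00000020702). The authors' annotation was another release, so it is not known which transcripts of that span the values cover. Il3 and Csf2, cytokine genes that act on myeloid cells, rose to 17.4 ± 4.21 and 15.6 ± 2.93 TPM from 5.66 ± 1.11 and 7.49 ± 2.53 TPM; they were the 2 called among the 3 kept type 2, type 17 and regulatory cytokine genes, and Tgfb1, lower when adjusted over the list alone, was not (-0.13, adjusted p = 0.0976; 0.0360 without DMSO replicate 3, and 0.0359 with medians of ratios and 0.0368 with quantile normalization). That list was not called (camera adjusted p = 0.506; 0.00901 with no filter); without ponatinib replicate 3, Il3 was under the minimum mean, 1 of 2 kept members was higher and the median was 0.46.

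Naive and stem-like memory genes had 13 of 20 kept members higher and 2 lower, with a median of 0.46; adjusted over the list alone, 13 were higher and 3 lower, and without DMSO replicate 3, 13 and 4. S1pr1, a receptor that lets T cells leave lymphoid organs, rose from 2.16 ± 0.740 to 24.1 ± 7.44 TPM (log2 fold change 2.98, SE 0.23, adjusted p = 1.91e-04), and its regulator Klf2 rose from 10.6 ± 1.34 to 40.5 ± 11.8 TPM. Tcf7, a transcription factor of memory T cells, rose from 117 ± 10.5 to 211 ± 22.7 TPM and Il7r, the IL-7 receptor, from 10.2 ± 6.07 to 37.1 ± 12.5 TPM. Ccr7, which guides naive T cells to lymph nodes, fell from 395 ± 43.3 to 229 ± 2.42 TPM. The list was not called (camera adjusted p = 0.115; 0.634 with an estimated correlation); its adjusted p was 0.0468 and 0.0464 without ponatinib replicates 2 and 3 and 0.0262 with medians of ratios. With no filter it was 0.00195, with a minimum mean of 1 TPM 0.00947 and with camera on ranks 0.0422. In the same libraries low-level B cell markers summed to 26.1, 31.9 and 31.2 TPM with ponatinib against 5.31, 6.27 and 19.9 TPM with DMSO.

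Inhibitory receptor genes split, with 3 higher and 3 lower of 8 kept members over all genes and adjusted over the list alone; the median was 0.05 (-0.05 with medians of ratios, from -0.02 to 0.11 with 1 library left out), the mean -0.22 and the camera direction down (adjusted p = 0.456). Lag3 fell from 146 ± 28 to 64.9 ± 2.12 TPM and Tigit from 84.9 ± 19.1 to 50.7 ± 2.28 TPM, whereas Cd160 rose from 66.1 ± 6.88 to 119.7 ± 4.09 TPM and Vsir from 32.2 ± 1.04 to 51.5 ± 6.76 TPM. Ctla4 fell by 1.81 on the log2 scale (adjusted p = 0.0169), with 236 TPM in DMSO replicate 3 against 71.1 and 58.5 TPM in the others. Its log2 fold change was -1.19 without DMSO replicate 3, and the call was lost without ponatinib replicate 1 or 3 (adjusted p of 0.0653 and 0.0511). No filter (0.0599) and robust empirical Bayes (0.0581) ended the Ctla4 call too. Pdcd1, encoding PD-1, was higher at 64.2 ± 0.863 against 55.0 ± 2.84 TPM (0.22, adjusted p = 0.0206), a call lost without DMSO replicates 1 and 2 (0.0633 and 0.0657), without ponatinib replicates 1, 2 and 3 (0.0557, 0.0643 and 0.0735) and with medians of ratios (0.0928). Havcr2 and Tox lay under the minimum mean; with no filter Havcr2 was higher, at 4.68 ± 0.335 against 0.478 ± 0.478 TPM (adjusted p = 0.00463), and Tox was at 9.13 ± 0.538 and 9.61 ± 0.730 TPM (0.674).

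**Figure D3:**
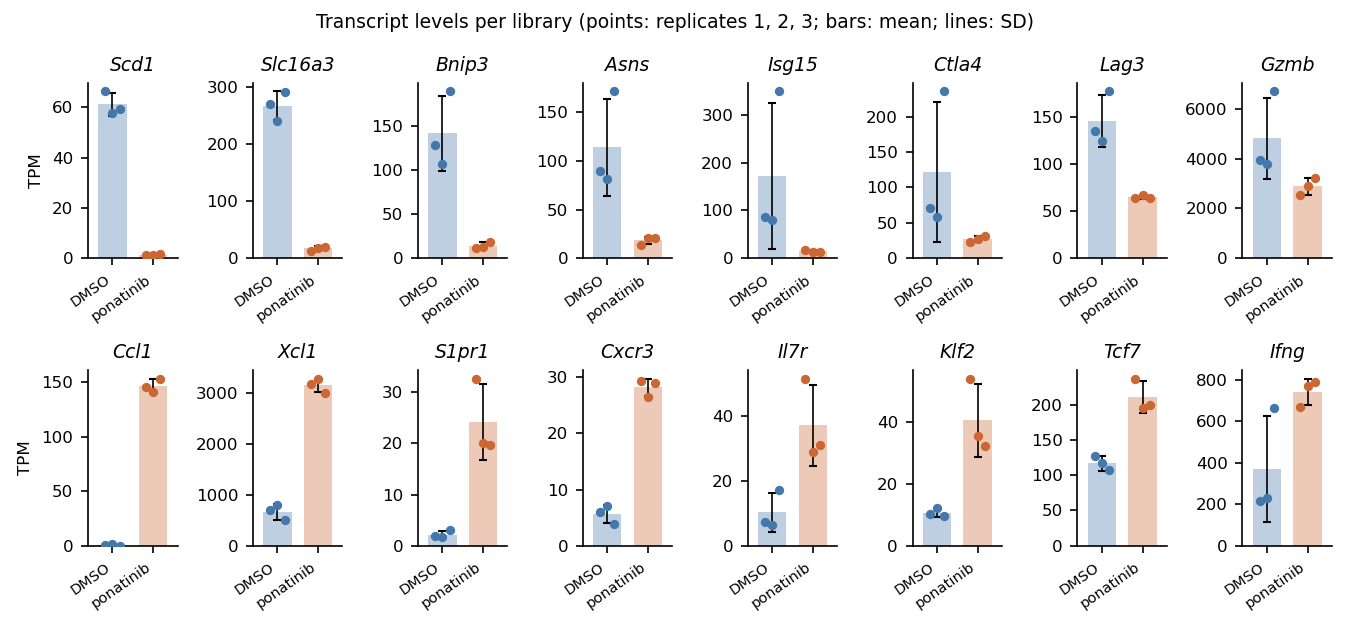
TPM (y axis, linear, with its own scale for each gene) of 16 genes in the 3 DMSO and 3 ponatinib libraries; points are libraries, bars are means and lines are the SD. Means were lower with ponatinib in the top panels and higher in the bottom panels, and DMSO replicate 3 is the highest DMSO library for Isg15 (349 TPM), Ctla4 (236 TPM), Gzmb (6696 TPM) and Ifng (665 TPM).

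Genes induced by the T cell receptor also went both ways, with 10 higher and 11 lower of 32 kept members, and 11 and 11 adjusted over the list alone. The median was 0.09 (-0.01 with medians of ratios, from 0.02 to 0.14 with 1 library left out), the mean -0.10 and the camera direction down (adjusted p = 0.170). With a minimum mean of 100 TPM the median was -0.45 and the list was called lower (adjusted p = 0.00170). With the minimum of 10 TPM and an estimated correlation, its camera adjusted p was 0.634. The costimulatory receptor genes Tnfrsf4 and Tnfrsf18 fell, from 372 ± 42.5 to 128 ± 11.7 TPM and from 289.5 ± 51.3 to 117 ± 10.8 TPM. Crtam, an adhesion receptor of activated T cells, rose from 72.4 ± 2.95 to 159 ± 7.96 TPM, and Tnfsf14 rose from 22.9 ± 0.392 to 35.8 ± 1.04 TPM. The transcription factor gene Irf4 fell by 0.45 on the log2 scale (adjusted p = 0.00759). Cd69 and Nr4a1 did not pass the test, at 73.1 ± 5.28 against 73.4 ± 15.5 TPM and 88.9 ± 4.58 against 101 ± 20.3 TPM (log2 fold changes of 0.01 and -0.17, and of 0.17 and -0.02 without DMSO replicate 3).

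Myc and Il2ra, which encodes the high-affinity IL-2 receptor chain, were lower by 0.48 and 0.45 on the log2 scale, with adjusted p of 0.0247 and 0.0281, and without DMSO replicate 3 their log2 fold changes were -0.31 and -0.30. Both calls were lost without ponatinib replicates 1, 2 and 3, with adjusted p of 0.0855, 0.0678 and 0.0591 for Myc and 0.0987, 0.0653 and 0.0596 for Il2ra. With no filter both were lost as well (0.0722 for Myc and 0.0802 for Il2ra).

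Among T cell receptor signalling components, 13 of 27 kept members were higher and 3 lower, also adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.456); with medians of ratios 9 were higher and 5 lower. Cd8a rose from 238 ± 9.41 to 346 ± 22 TPM, the kinase gene Fyn from 119 ± 3.03 to 154 ± 2.68 TPM and the adaptor gene Lcp2 by 0.33 on the log2 scale, while the phosphatase gene Ptpn6 fell by 0.25. Of 7 kept kinases known as ponatinib targets, Fyn and Abl2 were higher and 0 lower; adjusted over the list alone, 2 were higher and 1 lower. With medians of ratios Ripk2 and Ripk3 were called lower (adjusted p of 0.0436 and 0.0227), and Ripk3 was so without DMSO replicate 3 (0.0198). The kinase list had a median of -0.03, a mean of 0.06 and the camera direction down (adjusted p = 0.531). Abl2 was at 13.3 ± 0.495 against 9.17 ± 1.32 TPM (adjusted p = 0.0108; 0.0523 without ponatinib replicate 3). ERK feedback genes had 2 higher and 2 lower of 7 kept, and 3 and 2 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.290): Dusp6 rose by 0.64, and Ier3 and Dusp4 fell by 1.52 and 0.81 on the log2 scale. Spry1 was at 0.23 (adjusted p = 0.0494), a call lost without DMSO replicates 1 and 2 (0.117 and 0.120), without ponatinib replicates 1 and 2 (0.122 and 0.186), and with medians of ratios (0.224) and quantile normalization (0.215). The ERK list had 1 higher member without DMSO replicate 1 or 2 or ponatinib replicate 2, and a median from -0.33 without DMSO replicate 1 to 0.14 without DMSO replicate 3.

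Ribosome biogenesis and MYC target genes were the list called higher, with 17 of 27 kept members higher and 0 lower, also adjusted over the list alone, and a median of 0.28, or 0.18 above that of all kept genes. Ddx21 rose from 249 ± 4.83 to 316 ± 9.68 TPM and Nolc1 from 267 ± 3.93 to 339 ± 17.5 TPM. The camera adjusted p was 0.00116, and it was 0.634 with an estimated correlation. With medians of ratios 11 members were higher and 1 lower.

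Of DNA replication and G1/S genes, 12 of 35 kept members were higher and 0 lower, also adjusted over the list alone. Their median was 0.10, or -0.0055 relative to all kept genes (camera adjusted p = 0.169, and 0.00508 with no filter). With no filter the median of all tested genes was 0.03, so camera's reference lay lower there. Rrm2, a subunit of ribonucleotide reductase, rose from 185 ± 16.9 to 258 ± 14.7 TPM; Mcm5 was higher by 0.26 (adjusted p = 0.00418; 0.0559 with medians of ratios). Of mitosis and G2/M genes, 14 of 30 were higher and 0 lower, and 15 and 0 adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.0597; 0.634 with an estimated correlation). Kif23 and Kif20a, kinesins of cell division, rose by 0.45 and 0.34 on the log2 scale, and Mki67 was at 102 ± 3.04 against 104 ± 4.36 TPM (adjusted p = 0.713). The mitosis list's adjusted p was 0.0400 without DMSO replicate 3 and 0.0435 and 0.0420 without ponatinib replicates 1 and 2, and 0.0490 with the replicate block. It was 6.55e-04 with no filter, 0.0112 with a minimum mean of 1 TPM, 0.0360 with mitochondrially encoded genes removed and 0.0422 with camera on ranks. Without DMSO replicate 1 or ponatinib replicates 2 or 3 the replication list had 6, 7 and 6 higher members. The mitosis list without DMSO replicates 1 or 2 or ponatinib replicates 1, 2 or 3 had 8, 9, 9, 8 and 7. With medians of ratios the replication list had 6 higher and 1 lower and the mitosis list 8 and 1. Cyclin-dependent kinase inhibitor and quiescence genes had 0 higher and 3 lower of 7 kept, and 1 and 3 adjusted over the list alone, with a median of 0.06, a mean of -0.16 and the camera direction down (adjusted p = 0.168). Without DMSO replicate 3 it had 4 higher and 3 lower of 8 kept and a median of 0.19, and without DMSO replicates 1 or 2 it had 1 higher of 9, with a median of 0.02 in the latter case. Ccng2 and Klf6 fell by 0.79 and 0.66 on the log2 scale. Cdkn2d was at -0.35 (adjusted p = 0.0476), -0.23 without DMSO replicate 3, and lost its call without DMSO replicate 1 (0.0948) and without ponatinib replicates 1, 2 and 3 (0.0679, 0.117 and 0.160).

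Interferon response genes had 5 higher and 8 lower of 24 kept members, also adjusted over the list alone, with a median of 0.01 (-0.08 with medians of ratios, from -0.24 to 0.22 with 1 library left out), a mean of -0.37 and the camera direction down (adjusted p = 0.0614; 0.634 with an estimated correlation). Isg15, a ubiquitin-like protein induced by interferon, fell from 172 ± 153 to 14.7 ± 2.25 TPM (log2 fold change -3.12, SE 0.49, adjusted p = 0.00291), and Tap1 fell by 0.48, whereas Gbp3 and Irf1 rose by 0.90 and 0.40 on the log2 scale. In DMSO replicate 3 Isg15 was at 349 TPM against 86.8 and 80.9 TPM, and its log2 fold change was -2.44 without that library. Without DMSO replicate 3 the list had 10 higher and 5 lower members and a median of 0.22; its adjusted p was 0.0132 and 0.0325 without DMSO replicates 1 and 2 and 0.0122 without ponatinib replicate 1. With no filter and with a minimum mean of 1 TPM it was 0.00901 and 0.0103, and with a minimum mean of 100 TPM the median was 0.14. Without ponatinib replicates 2 and 3, 4 members were lower each time.

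Cytokine receptor and STAT5 target genes had 3 higher and 4 lower of 21 kept, also adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.0793; 0.634 with an estimated correlation; 0.0244 and 0.0357 without DMSO replicates 1 and 2). It had 10 higher and 5 lower without DMSO replicate 3 and a median of 0.21, and a median of -0.14 without DMSO replicate 2. Il12rb2, an IL-12 receptor chain, fell from 125 ± 51.4 to 33.5 ± 3.73 TPM, Pim2 fell by 0.81, and Il2rg rose by 0.56 on the log2 scale. Homing and adhesion genes had 4 higher and 1 lower of 13 kept, also adjusted over the list alone, with a median of 0.18, or 0.17 to 0.28 with 1 library left out (camera adjusted p = 0.170; 0.00393 with no filter and 0.0146 with a minimum mean of 1 TPM). The chemokine receptor gene Cxcr3 rose from 5.63 ± 1.65 to 28.2 ± 1.56 TPM and the integrin gene Itgal from 121 ± 0.988 to 184 ± 4.54 TPM, Ly6c2 fell by 0.81 on the log2 scale, and Cd44 was at 62.1 ± 7.73 against 54.7 ± 5.25 TPM (adjusted p = 0.221).

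Oxidative phosphorylation genes had 2 higher and 2 lower of 29 kept members, and 0 and 0 adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.0793; 0.0162 without DMSO replicate 3). The 2 higher were Cycs (0.23) and Sdhd (0.25) and the 2 lower Atp5b (-0.15) and Ndufv1 (-0.17), and each lost its call without at least 1 library: Cycs had an adjusted p of 0.0679 and Sdhd of 0.0944 without ponatinib replicate 3, and Atp5b of 0.11 and Ndufv1 of 0.139 without DMSO replicate 1. With medians of ratios 0 were higher and 10 lower and the list was called lower (adjusted p = 0.00910). Quantile normalization gave 1 and 6 and an adjusted p of 0.0256. The adjusted p was 0.0481 with a minimum mean of 100 TPM, 0.0210 with array weights and 0.0422 with camera on ranks. As deposited, the adjusted p was 0.634 with an estimated correlation. The list had 1 higher and 0 lower without DMSO replicate 1 or ponatinib replicates 1 or 2, 2 and 1 without DMSO replicate 2, and 0 and 1 without ponatinib replicate 3. Unfolded protein response genes had 4 higher and 1 lower of 16, also adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.779); Calr rose by 0.47 and Herpud1 fell by 0.67 on the log2 scale. Without DMSO replicate 3 that list had 10 higher and 1 lower and a median of 0.23, against 0.10 without DMSO replicate 2; without any 1 of the other libraries 2 and 1, and with medians of ratios 2 and 2. Heat shock genes had 6 higher and 0 lower of 10, also adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.169), among them the chaperone genes Hspd1 and Hsph1 (0.37 and 0.54). Of these 10, 3 were higher and 1 lower with medians of ratios, 3 and 0 without ponatinib replicate 2, and 6 and 1 without DMSO replicate 3.

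Targets of p53 had 8 higher and 0 lower of 14 kept members, also adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.25); Sesn1 rose from 9.11 ± 1.05 to 14.6 ± 0.965 TPM and Plk2 from 20.2 ± 4.26 to 32.3 ± 2.83 TPM. With medians of ratios 4 p53 targets were higher and 2 lower, without ponatinib replicates 2 or 3 there were 4 higher and 0 lower, and without DMSO replicate 1 there were 7 and 1. BCL2 family genes, regulators of apoptosis, had 6 higher and 0 lower of 8 kept, also adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.0793; 0.634 with an estimated correlation). Its adjusted p was 0.0262 with medians of ratios, 0.0439 with quantile normalization and 0.0384 without ponatinib replicate 1, and without ponatinib replicate 3, 3 were higher. The pro-apoptotic Bcl2l11 and the anti-apoptotic Mcl1 rose by 0.51 and 0.44 on the log2 scale. Also among the 6 were Bcl2a1b and Bcl2a1d, at 0.41 and 0.51, which are almost alike and may not count as separate signals. The call of Bcl2a1d was lost without ponatinib replicate 3 (limma adjusted p = 0.0564). Other genes with large changes were Anxa2, which fell from 183 ± 67.7 to 43.5 ± 4.07 TPM, and Mbnl1 and Txnrd1, an RNA-binding protein and thioredoxin reductase, which rose from 141 ± 13.5 to 284 ± 30.5 TPM and from 89.4 ± 18.3 to 167 ± 12.4 TPM.

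Markers of other blood cells were mostly under the minimum mean. Among B cell markers, 3 of 5 kept were higher and 0 lower, also adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.290; 0.00901 with no filter and 0.0432 with a minimum mean of 1 TPM). Cd74 was 123 ± 7.11 against 85.0 ± 2.57 TPM, Cd79b 13.4 ± 0.832 against 8.11 ± 1.39 TPM, and Igkc 25.3 ± 1.83 against 7.99 ± 7.91 TPM. H2-Ab1 went the other way without a call, at 7.07, 9.82 and 10.5 TPM with ponatinib against 12.7, 10.6 and 34.1 TPM (-0.82, adjusted p = 0.122; -0.33 without DMSO replicate 3). The call of Igkc (1.95, adjusted p = 0.0275) was lost without DMSO replicate 1 (0.0754) and without ponatinib replicates 1, 2 and 3 (0.0743, 0.0761 and 0.0891), and its log2 fold change was 1.31 and 2.64 without DMSO replicates 2 and 3. No filter (0.0848) and robust empirical Bayes (0.0810) ended the Igkc call too. The B cell markers under 10 TPM summed to 5.31, 6.27 and 19.9 TPM in the DMSO libraries and 26.1, 31.9 and 31.2 TPM with ponatinib. The low CD4 T cell markers summed to 7.66, 6.05 and 15.4 against 21.6, 21 and 16.6 TPM, the myeloid markers to 5.54, 5.74 and 9 against 15.6, 15 and 12 TPM, and the erythroid and platelet markers to 0.91, 1.2 and 1.99 against 8.47, 4.25 and 4.97 TPM. NK markers overlapped, at 11.8, 16.6 and 14.3 against 14.2, 10.9 and 14.2 TPM. The mean was higher with ponatinib in 13 of 14 low B cell, 5 of 6 CD4 T cell, 19 of 24 myeloid, 11 of 13 NK and 7 of 9 erythroid and platelet markers. All 3 ponatinib libraries were higher in 5, 3, 10, 6 and 3 of them, and 1 myeloid and 1 NK marker were lower in all 3. The same shares over all genes under 10 TPM were not computed, so the counts do not show a rise particular to these markers. With no filter, 2082 of 15420 genes were called higher and 849 lower. Leaving out the most abundant low member of each list, the sums were still higher in all 3 ponatinib libraries for the B cell, myeloid and erythroid lists and overlapped for the CD4 T cell list. The NK overlap rested on Klrc1, chosen after its values were seen: without it the sums were 1.73, 2.3 and 2.34 against 7.12, 4.47 and 5.72 TPM.

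Of the CD4 T cell list only Ccr4 was kept (0.18) and was not called; Foxp3, the transcription factor of regulatory T cells, was at 1.42 TPM or less in the DMSO libraries and at 12.8, 10.7 and 7.33 TPM with ponatinib, a gene chosen after its values were seen. Of the NK list Klrk1 and Klrd1 were kept: Klrk1, which CD8 T cells also express, fell from 62.7 ± 18.2 to 16.2 ± 1.57 TPM, and Klrd1 was at 0.01; without ponatinib replicates 1 or 2, 3 were kept and 2 lower. No myeloid, erythroid or sex-linked member was kept. The Y-linked transcripts in the table were at most 0.143 TPM in every library. Of 9 kept RNA quality transcripts, all mitochondrially encoded, 0 were called, also adjusted over the list alone, with a median of -0.11 (0.04, 0.10 and -0.51 without DMSO replicates 1, 2 and 3; camera adjusted p = 0.169; 0.634 with an estimated correlation). Without DMSO replicate 3, 8 were lower and the list was called lower (adjusted p = 4.69e-10); with array weights it was called lower as well (2.37e-04).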

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

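Gene rows alone, a minimum mean of 1 TPM and removal of mitochondrially encoded genes were chosen only after the results were seen; the other settings were fixed earlier. The number of higher genes, 1859, was 1059 with medians of ratios, 446 with a minimum mean of 100 TPM, 3414 with array weights and 204 with a minimum fold of 1.2, and ranged from 1037 to 2659 with 1 library left out. The number of lower genes, 622, was 1138 with medians of ratios, 989 with quantile normalization, 144 with a minimum mean of 100 TPM, 984 with array weights and 171 with a minimum fold of 1.2, and ranged from 433 to 668 with 1 library left out. A higher minimum tests fewer genes, 1345, and a minimum fold is a stricter test; for the other settings the cause was not tested.

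The number of lists called higher, 1, was 4 with medians of ratios, 2 with quantile normalization, 8 with no filter, 6 with a minimum mean of 1 TPM, 2 with mitochondrially encoded genes removed, 2 with the replicate block, 11 with fry, 3 with camera on ranks and 0 with an estimated correlation, and ranged from 1 to 3 with 1 library left out. Fry tests a list against 0, and camera tests it against the other kept genes. The median of all kept genes lay at 0.10, so fry's count is not the same measure. Camera's reference changes with the filter as well. The median of all tested genes was 0.03 over 15420 genes with no filter. With a minimum mean of 1 TPM it was 0.09 over 10244 genes. List results under these 2 settings therefore rest on another set of genes and are not added support. The number called lower, 5, was 0 with an estimated correlation and 5 to 7 under the other settings and with 1 library left out. The preset correlation was 0.01. Estimated correlations were 0.71 for glycolysis, 0.58 for hypoxia, 0.84 for ATF4, 0.31 for sterol and 0.19 for fatty acid genes. For ribosome biogenesis genes the estimate was 0.48. A higher correlation gives a larger p, so these calls depend on the preset value. For the other settings the cause was not tested. None of the 5 lower lists or the ribosome biogenesis list lost its call when a library was left out, and the fatty acid list lost it with a minimum mean of 100 TPM (adjusted p = 0.138). With that minimum the list of genes induced by the T cell receptor was called lower (adjusted p = 0.00170). With the minimum of 10 TPM and an estimated correlation, the camera adjusted p of that list was 0.634. The lists that fry added were those of naive and memory genes, T cell receptor signalling, replication, mitosis, heat shock, type 2 cytokines, homing, p53, BCL2 and B cells.

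No gene and no list was called in opposite directions under any setting. Over 129 named genes there were 2630 comparisons with an alternative: 2433 kept the direction and the side of the threshold, 152 lost a call, 56 of them with the minimum fold of 1.2, 25 gained one and 20 changed sign without a call. Of 611 comparisons of lists, 542 were the same, 7 lost a call, 52 gained one and 10 changed sign without a call. Rescaling to the same total moved nothing because TPM already share one, so it tests nothing. The first component held 80.9% of the variance over the 1000 most variable genes.

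Replicate numbers are shared between groups, but the deviations of same-numbered libraries correlated by -0.1, 0.114 and 0.0231, and 2 of the 6 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate block 1791 genes were higher and 623 lower, and 2 lists were higher and 5 lower. The list gained was that of mitosis (adjusted p = 0.0490). Of the named genes, Spry1, Cdkn2d, Atp5b and Ndufv1 lost their calls with the block (limma adjusted p of 0.0768, 0.0610, 0.0534 and 0.0593). TPM keep no depth, so for genes near 10 TPM it is not known how much of the spread between these 6 libraries is counting noise.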

Other observations

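The tests of 8 added gene lists, of DMSO replicate 3, of cell division and of residual cells were chosen only after the results of the fixed lists were seen; those of the splits, of GC content and length, and of the pentose phosphate genes were written before their own results were seen.

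Further gene groups were looked at with 8 lists chosen after seeing the data and adjusted among themselves, and the members named were chosen after their values were seen. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 9 of 16 kept members lower and 1 higher, with a median log2 fold change of -0.25 (camera adjusted p = 2.11e-05; 0.342 with an estimated correlation): Gars fell from 363 ± 44.8 to 225 ± 10.1 TPM and Nars from 340.1 ± 55.1 to 213 ± 13.0 TPM, whereas Hars rose by 0.20. No synthetase was higher with medians of ratios, with quantile normalization, or without DMSO replicate 1 or ponatinib replicates 2 or 3, and 2 were without DMSO replicate 3. Pentose phosphate pathway genes had 3 of 7 lower and 0 higher, with a median of -0.15 (camera adjusted p = 0.00275; 0.280 with an estimated correlation), among them Pgls, which fell from 146 ± 5.32 to 105 ± 4.10 TPM. Cytosolic ribosomal protein genes had 8 of 40 lower and 0 higher, with a median of -0.06 (camera adjusted p = 1.49e-06; 0.307 with an estimated correlation); Rps2 fell from 8638 ± 289 to 6815 ± 244 TPM. With medians of ratios 0 were higher and 23 lower, and with quantile normalization 6 and 2. Leaving out DMSO replicates 1, 2 or 3 gave 3, 5 and 10 lower, with 3 higher in the last case, and leaving out ponatinib replicates 1, 2 or 3 gave 3, 2 and 2 lower.

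Purine and pyrimidine synthesis genes had 6 of 15 higher and 0 lower (median 0.15, camera adjusted p = 0.182), or 3 and 1 with medians of ratios, with Ctps up from 67.9 ± 2.57 to 84.8 ± 3.53 TPM; 2 or 3 were higher without any 1 library other than DMSO replicate 3, and 5 higher and 1 lower without that one. Proteasome genes had 6 of 25 higher and 0 lower (median 0.06, or -0.04 relative to all kept genes, camera adjusted p = 0.707). With medians of ratios 1 was higher and 3 lower, and with quantile normalization 1 and 1. Without DMSO replicate 1 or ponatinib replicates 2 or 3, 1 was higher, and without DMSO replicate 2, 3 were. Lysosome genes had 4 higher and 4 lower of 19 (median -0.01, from -0.06 to 0.01 with 1 library left out, adjusted p = 0.0999), with 2 lower without DMSO replicate 1 or ponatinib replicate 3, 1 lower without ponatinib replicate 2, and 2 higher and 6 lower with medians of ratios. MHC class I genes had 2 higher and 0 lower of 14 (median -0.05, from -0.11 to 0.02 with 1 library left out, adjusted p = 0.14), but 1 and 5 with medians of ratios and 2 and 5 with quantile normalization; 4 were higher without DMSO replicate 3, 1 was higher without any 1 of the other libraries, and 2 were lower without DMSO replicate 2. Of the circadian clock genes 2 were kept, Per1 and Cry1, and 0 were called.

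The 6 libraries can be split into groups of 3 in 10 ways. The real split gave 2481 genes past the threshold and the highest of the others 0. The 1 of the 10 splits with as many was the real one itself, and 10 splits are too few for a share under 0.05. Every other split puts libraries of both treatments in a group, so the treatment difference adds to the spread within groups. A count of 0 there does not show how many calls arise without a treatment effect.

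The first pattern weighed is the joint fall of hypoxia, glycolysis, ATF4, sterol and fatty acid genes, with 75 of 88 pooled members lower and a pooled median of -0.87 relative to all kept genes. The tables argue against DMSO replicate 3 as its source (the pooled median was -0.87 without that library too) and against a trend with GC content and transcript length (-0.81 after its removal). For less cell division, pooled replication, mitosis and ribosome biogenesis genes lay 0.0672 above all genes. Taken alone, these lists lay at -0.0055, 0.099 and 0.18 relative to all kept genes. The values argue against a joint fall of these transcripts, but division itself was not measured and less of it stays open. A hypothesis is lower mTORC1-dependent transcription, which may lower pentose phosphate genes as well: their median lay at -0.25 relative to all kept genes (limma camera adjusted p = 0.00275; adjusted p = 0.28 with an estimated correlation) with 3 of 7 members lower, but purine synthesis genes were not lower, and ribosome biogenesis genes were higher. Oxygen in the cultures, cell density and the medium were not measured and remain open as other sources.

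DMSO replicate 3 stood apart from DMSO replicates 1 and 2, with higher interferon genes, Gzmb and Ctla4 and a lower mitochondrial share. A swap or a wrong treatment label is argued against, since over the 3312 genes called between the other 5 libraries that were also kept over all 6 it lay 0.0633 of the way from the DMSO to the ponatinib mean. Rescaling by its lower mitochondrial share is argued against as the whole source of the interferon difference: with mitochondrially encoded genes removed, interferon genes had a median difference of 0.46 (lower quartile 0.15) against 0.02 for all kept genes, and 22 of 24 were higher. A first bound of 0.5 for that median was not reached, and the bound now used, a lower quartile above the median of all genes, was set after the value was seen. No biological explanation was tested, since the labels give no difference between the DMSO libraries.

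Summed low-level transcripts of B, myeloid and erythroid cells were higher with ponatinib. The mean was higher in 13 of 14, 19 of 24 and 7 of 9 low members and in 11 of 13 low NK markers. All 3 ponatinib libraries were higher in 5, 10, 3 and 6 of them. Mpeg1, a myeloid marker, was lower in all 3. The same shares over all genes under 10 TPM were not computed, so these counts do not set the markers apart from other low genes. Without H2-Aa, its most abundant low member, the B cell sums were 13.5, 18.1 and 18.9 TPM with ponatinib against 4.19, 4.02 and 12.4 TPM. H2-Ab1, another B cell marker, was lower without a call, by 0.82 on the log2 scale or 0.33 without DMSO replicate 3. A larger share of residual other cells with ponatinib is a candidate explanation that stays open: summed low markers were higher in all 3 ponatinib libraries for 3 of the 4 lists of B, myeloid, NK and erythroid cells, and the NK sums overlapped. That overlap rested on Klrc1, which CD8 T cells also express, at 7.31 ± 1.07 against 12.1 ± 2.12 TPM; without it the NK sums were 7.12, 4.47 and 5.72 TPM with ponatinib against 1.73, 2.3 and 2.34 TPM. The cells had been purified as naive CD8 T cells, which should remove these types, and Ighm was between 209 and 274 TPM in all 6 libraries. Klrc1, Ighm, Mpeg1 and H2-Aa, and the sums without a member, were chosen after the values were seen. Expression of such genes by the CD8 T cells themselves was not tested and cannot be told apart from residual cells in these data.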
